A study of Mus musculus with 4 samples.

How the data were processed

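RNA was measured in 4 libraries of small-intestinal organoids from 2 mice, each mouse giving 1 culture with DMSO and 1 with 2 µM GW3965 for 6 h. Per the labels' protocols, libraries were made with a stranded poly-A kit (TruSeq) and sequenced on a HiSeq-2500 as single-end reads of 50 bp, with RNA integrity numbers above 8. The extraction text in the labels speaks of colon samples, while the tissue label and the growth protocol name small-intestinal organoids, and the latter were followed.

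The submitters' processing notes name kallisto (no version), CASAVA 1.7, FastQC (no version) and the genome build mm10. Per the file headers, the authors deposited kallisto estimated counts and TPM for each transcript and library; the estimated counts are not normalised, and the TPM are relative to the whole library. A series-wide table deposited by the authors holds the same estimated counts per transcript rounded to whole numbers (largest gap 0.5). The authors also deposited a table of log2 CPM for 8524 gene symbols; its filter and the scaling between libraries are not given in the sources used here. The annotation release behind the transcript identifiers, and the use of strand in counting, are likewise not given.

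Of 88198 transcripts, 86119 (97.6%) matched the GENCODE M21 annotation of GRCm38, and their estimated counts were summed over 30284 genes and rounded to whole numbers. The 2079 unmatched transcripts held 0.69 to 0.85% of the counts of a library and stayed out of the library sizes and tests. The design had foreseen gene counts in the series-wide table; since that table is per transcript, the summed transcript counts served as the main values and sums of the rounded table as an alternative. kallisto divides reads that fit several transcripts between them, so counts of near-identical copies are uncertain, and the counts of a pseudogene can rise or fall without a change in its own transcript.

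Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 2 libraries of each treatment were compared without a block (2 residual degrees of freedom, prior degrees of freedom 7.78). Normalised CPM use the TMM-scaled library sizes, and errors beside log2 fold changes are standard errors derived from the F statistic. The same-numbered libraries come from the same mouse, per the labels, so a fit with the mouse as a block (1 residual degree of freedom, with an infinite prior) was run beside it. An infinite prior gives each gene the variance of genes of similar expression. A blocked p therefore does not reflect the gene's own spread between cultures. As a check of the pairing, the deviations of same-mouse libraries from their group means correlated at 0.072 across genes. Libraries were also compared with each other by a chi-square of their counts, and no pair agreed within sampling noise (chi-square per degree of freedom from 10.7 to 78.9).

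29 gene lists with 452 genes were fixed before the data were examined and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists; a list needed at least 3 tested members. A list's median in a mouse was placed among those of 10000 random lists matched on mean expression. Random lists do not keep the correlation between a list's members, so a percentile does not measure the spread between cultures. The lists held LXR targets; genes of fatty acid synthesis, cholesterol synthesis, lipid absorption, bile acids, xenobiotics, PPAR, retinoids, Wnt, EGF receptor ligands, proliferation, regeneration and stress or immune responses; markers of epithelial, immune and mesenchymal cells and of gut regions; and mitochondrial genes. The mice were compared with treatment as a covariate. Transcripts were tested as genes were. The genes named in the text are the called genes with the largest changes (up to 12 each way, at a mean log2 CPM of at least 1 and with the same sign in both mice, which 7 genes met), up to 4 members of each list with the smallest p, and 21 genes fixed in advance, of which 1 is not reported here; genes outside these rules are said to have been chosen after their values were seen.

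On simulated counts for the comparison of 2 libraries against 2 with 13602 genes, the unblocked test recovered 61% of 100 genes changed 2-fold and 94% of 100 genes changed 4-fold, with 18 false calls among 173. The blocked test recovered 68% and 94%, with 24 false calls among 186. The changes were planted in genes at a mean of at least 1 CPM, with no mouse effect and no outlying library. Of unchanged simulated genes, 4.98% had an unadjusted p under 0.05 in the unblocked test, against 143 of 13602 genes in the data. Recovery in the data, where 8 genes were called, can therefore be lower. The depth of 16572359 to 19486547 counts per library gives intervals and floors for counting error alone, since reads carry no molecular identifiers. A gene at 0 counts is set against a floor of 3 counts per library.

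Alternatives covered other scaling factors, DESeq2 1.42.0, edgeR's likelihood ratio test, limma-voom, other filters, the rounded counts, the authors' log2 CPM table, a fold of at least 1.5, the mouse as a block and leaving out each library. A fit that leaves 1 library in a group assumes the spread of that library. Such fits called more genes than the main fit, so a pass there does not show that a call is stable. They also hold unequal numbers of libraries per mouse, so a difference between the mice can enter the change with GW3965. Sets of protein-coding genes alone and of all genes but the mitochondrial ones, and the block combined with protein-coding genes or with an estimated correlation, were added after seeing the data. Sequence sharing was measured as the share of a gene's 31-mers, on either strand, that occur in another gene's transcripts among those matched. Trends with GC content and length were removed within each mouse by lowess in statsmodels 0.14.6, for the 11488 of 11494 genes with these values. Intervals used scipy 1.17.1, tables pandas 2.3.3 and figures matplotlib 3.10.9 under Python 3.11.15.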

Results

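Poly-A RNA was sequenced from small-intestinal organoids, which are 3-dimensional epithelial cultures grown in Matrigel from intestinal crypts. The crypts came from 2 male C57BL/6J mice. Crypts of each mouse were kept for 6 h either with the vehicle DMSO or with 2 µM GW3965, a synthetic agonist of the liver X receptors (LXRα, encoded by Nr1h3, and LXRβ, encoded by Nr1h2), which are nuclear receptors for oxidised sterols. Each treatment therefore had 2 libraries, 1 per mouse, and the comparison asks which transcripts change when LXR is activated in the epithelium. The total estimated count was 19014131 for DMSO and 16572359 for GW3965 in mouse 1, and 19360706 for DMSO and 19486547 for GW3965 in mouse 2. Between 18147 and 18394 genes had a count above 0 in a library, and 13602 genes entered the tests.

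The GW3965 library of mouse 1 stood apart from the other 3. Transcripts of the mitochondrial genome took 14.01% of its gene counts (95% Wilson interval 13.995 to 14.029), against 7.60% in the DMSO library of the same mouse (7.59 to 7.61), 9.43% in the DMSO library of mouse 2 (9.41 to 9.44) and 8.74% in the GW3965 library of mouse 2 (8.72 to 8.75). These intervals cover counting error alone. The first principal component held 51.3% of the variance of log2 CPM, with this library at 43.1 and the others between -25.2 and -7.97. Its correlation with the other libraries across genes was 0.973 to 0.979, and that among the other 3 was 0.983 to 0.988.

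GW3965 raised a small set of genes of sterol transport and lipid metabolism in both mice. Abca1, a cholesterol exporter, went from 1.11 ± 0.91 to 51.6 ± 12.5 normalised CPM (counts scaled to a common library size; mean ± SD, n = 2 per group), 46.7-fold. The 2 DMSO libraries were at 0.462 and 1.75 CPM, and the log2 fold change of 5.54 moved to 4.88 without the DMSO library of mouse 1 and to 6.78 without that of mouse 2. Abcg1, another sterol exporter, went from 1.33 ± 0.08 to 27.2 ± 2.11 CPM, 20.4-fold. Abcg5 and Abcg8, the 2 subunits of the sterol transporter that returns sterols to the gut lumen, rose 4.18-fold and 4-fold, from 56.8 ± 7.35 to 237.7 ± 47.4 CPM and from 30.7 ± 2.22 to 123 ± 11 CPM. Srebf1, the gene of a transcription factor for fatty acid synthesis, rose 5.78-fold, from 75.7 ± 3.81 to 437 ± 55.8 CPM. Scd2, a stearoyl-CoA desaturase, rose 7.5-fold, from 63.3 ± 14.8 to 475 ± 187 CPM, and Ppara, the gene of a fatty-acid-activated nuclear receptor, rose 4.34-fold, from 4.2 ± 0.16 to 18.2 ± 3.10 CPM.

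In edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over all genes tested, these 7 genes were past the adjusted p of 0.05. The log2 fold change and its standard error were 4.35 ± 0.25 for Abcg1 (adjusted p = 0.000157), 5.54 ± 0.43 for Abca1 (0.00134), 2.53 ± 0.24 for Srebf1 (0.00525), 2.00 ± 0.20 for Abcg8 (0.00581), 2.91 ± 0.33 for Scd2 (0.0142), 2.12 ± 0.24 for Ppara (0.0142) and 2.06 ± 0.24 for Abcg5 (0.0146). All 8 called genes were higher with GW3965 in each mouse, and 0 genes were lower. At an unadjusted p under 0.05, 91 genes were higher and 52 lower, 143 of 13602 tested. That share is under the 0.05 that a calibrated test gives when no gene changes. The unadjusted p thus ran high, and a gene that did not pass is not shown to be unchanged. DESeq2 called 17 higher and 3 lower, limma-voom 14 and 6, and edgeR's likelihood ratio test 20 and 9. The eighth gene, Gm16378, a processed pseudogene on chromosome 8 (122841731 to 122842072), is named because of the count and was chosen after its values were seen. It had 0 counts in both DMSO libraries and 27 and 61 in the GW3965 libraries, which makes it at least 15.2-fold higher against a floor of 3 counts per library (adjusted p = 0.0472). It shared 65.4% of its 31-mers with other genes, most of them with Eif1, so its reads cannot be assigned to it with certainty.

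With the mouse added to the model as a block, 48 genes were past the threshold, 31 higher and 17 lower, and all 8 genes above were among them. The infinite prior of this fit leaves a gene's own disagreement between the mice out of its p. DESeq2 with the same block called 12 genes, without Gm16378. Of the 48, 44 had the same sign in both mice, and 13 had 0 counts in both libraries of 1 treatment. With protein-coding genes alone the blocked fit called 29. The test without the GW3965 library of mouse 1 called 54 genes, 30 higher and 24 lower, and these too included all 8. Leaving out the DMSO library of mouse 2 also gave 54 genes and ended the call of Abcg5 (adjusted p = 0.071). Without the DMSO library of mouse 1 there were 38 calls, and without the GW3965 library of mouse 2 there were 84.

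On the mouse genome build GRCm38 (mm10; GENCODE M21 annotation), Abca1 lies on chromosome 4 (53030787 to 53159895), Abcg1 on chromosome 17 (31057675 to 31117988), Srebf1 on chromosome 11 (60199089 to 60222581), Scd2 on chromosome 19 (44293674 to 44306864) and Ppara on chromosome 15 (85734983 to 85802819). Abcg5 (84658234 to 84683011, minus strand) and Abcg8 (84676302 to 84700333, plus strand) lie beside each other on chromosome 17 and overlap. Abcg5 shared 1.94% of its 31-mers with Abcg8, and whether strand was used in the counting is not given in the sources used here, so reads of the overlap are not assigned to either with certainty. Srebf1 likewise shared 1.38% of its 31-mers with Rai1 on the other strand. Scd2 shared 4.87% of its 31-mers with its relative Scd3.

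**Figure D1:**
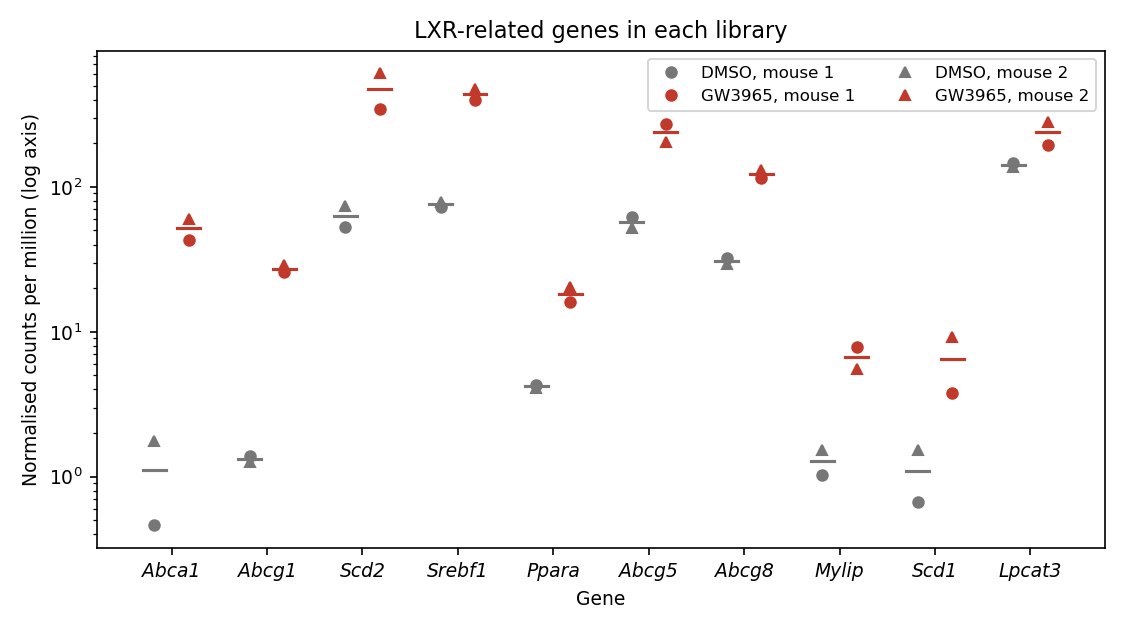
Normalised CPM (log axis) of 10 genes in each library; grey marks are DMSO and red marks GW3965, circles mouse 1 and triangles mouse 2, and horizontal bars are group means (n = 2). The GW3965 marks lie above the DMSO marks for every gene drawn, from 1.11 to 51.6 CPM on average for Abca1 and from 142 to 239 CPM for Lpcat3, which did not pass over all genes.

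Of the 22 LXR targets listed before the data were examined, 17 were expressed enough to be tested. Over all genes 6 rose and 0 fell, 10 rose when adjusted over the list alone, and 16 of the 17 had a positive log2 fold change. The list as a whole stood above the other genes in the camera test (adjusted p = 3.87e-45, preset correlation of 0.01), with a median log2 fold change of 0.75. With an estimated correlation the list gave an adjusted p = 0.200. Mylip, a ubiquitin ligase, and Scd1, a second desaturase, were among the 11 members not past the threshold over all genes. Without the block, Mylip had 1.28 ± 0.36 CPM with DMSO and 6.65 ± 1.62 with GW3965 (log2 fold change 2.37 ± 0.36, adjusted p = 0.0766), and its blocked adjusted p was 8.66e-07. The log2 difference of Mylip was 2.80 in mouse 1 and 1.77 in mouse 2. Fits without 1 library also called it, but they assume the spread of the lone library and do not show that the call is stable. Scd1 had 1.10 ± 0.62 and 6.45 ± 3.78 CPM (2.55 ± 0.52, adjusted p = 0.338), with a blocked adjusted p of 2.72e-07. The log2 difference of Scd1 was 2.32 in mouse 1 (0.668 and 3.78 CPM) and 2.49 in mouse 2 (1.54 and 9.13 CPM). Fits without 1 library hold unequal numbers of libraries per mouse, so the difference in level between the mice enters them. In such fits its log2 fold change was 3.05 without the GW3965 library of mouse 1 and 3.26 without the DMSO library of mouse 2. It was 2.07 without the DMSO library of mouse 1 and 1.77 without the GW3965 library of mouse 2.

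Lpcat3, a phospholipid-remodelling enzyme, had 142 ± 6.11 CPM with DMSO and 239 ± 61.7 with GW3965 (log2 fold change 0.75 ± 0.25, adjusted p = 0.99986), and it overlaps Emg1 on the other strand. Adjusted over the list alone its p was 0.0207. Its log2 difference was 0.42 in mouse 1 and 1.04 in mouse 2. Over all genes its adjusted p was 0.00151 without the GW3965 library of mouse 1, 0.112 without the GW3965 library of mouse 2, and 0.99995 and 0.9998 without the DMSO libraries of mouse 1 and mouse 2. The receptors themselves, Nr1h2 and Nr1h3, had log2 fold changes of 0.10 ± 0.18 and 0.04 ± 0.22. Neither passed the test. Both were expressed, with 52.5 ± 0.40 CPM for Nr1h2 and 16.0 ± 1.19 CPM for Nr1h3 in the DMSO cultures.

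Genes of the cholesterol synthesis list were lower as a group with GW3965. All 26 listed genes were tested and all 26 had a negative log2 fold change, with 24 negative in both mice. The list's median log2 fold change was -0.55 (camera adjusted p = 1.33e-29), and with an estimated correlation its adjusted p was 0.705. In mouse 1 the median was -0.68 and in mouse 2 it was -0.39, each below all 10000 random lists matched on expression (percentile 0). No single member passed the threshold over all genes or adjusted over the list alone (0 of 26 in both, edgeR), and DESeq2 and limma-voom also called 0. At an unadjusted p under 0.05, 11 of the 26 were lower. The members with the smallest p were Mvd, mevalonate diphosphate decarboxylase (83.9 ± 11.5 and 45.6 ± 8.90 CPM, log2 fold change -0.88 ± 0.21, adjusted p = 0.958), Mvk, mevalonate kinase (-0.72 ± 0.21), and Idi1, an isopentenyl diphosphate isomerase (-0.78 ± 0.24). Mvd overlaps Gm20388 on the other strand, and Idi1 shared 18.8% of its 31-mers with other genes. The list stayed lower with GW3965 when any 1 library was left out. Those fits assume the spread of the lone library and hold unequal numbers of libraries per mouse. They do not show that the call is stable.

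**Figure D2:**
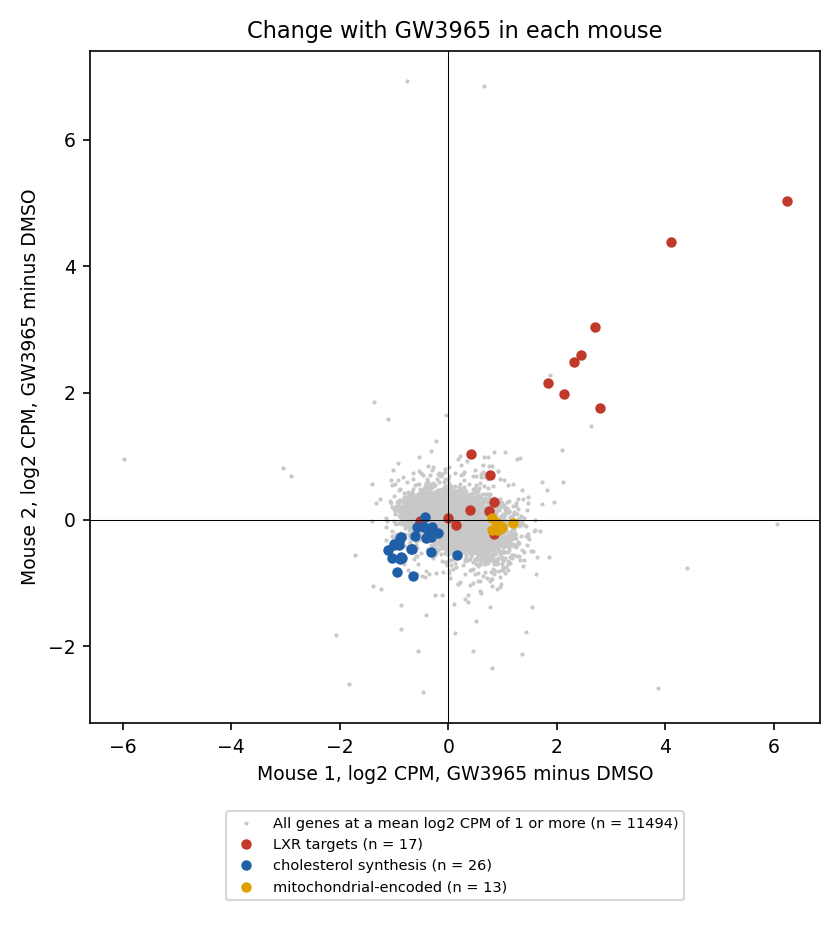
Log2 CPM difference between GW3965 and DMSO in mouse 1 (x axis) and mouse 2 (y axis); each point is a gene, with 11494 genes at a mean log2 CPM of at least 1 in grey, 17 LXR targets in red, 26 cholesterol synthesis genes in blue and 13 mitochondrial genes in yellow. The most changed LXR targets lie at the upper right, most cholesterol synthesis genes lie below 0 on both axes, and the mitochondrial genes are higher in mouse 1 with a median of 0.92 and near 0 in mouse 2 with -0.09.

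Fatty acid genes differed in direction within their lists and between the mice. In the fatty acid synthesis list 1 of 24 tested members rose over all genes (Scd2), 3 rose when adjusted over the list alone, 13 were positive and 11 negative. Its median was 0.02 with a camera adjusted p of 0.0386 (adjusted p = 0.820 with an estimated correlation), and its adjusted p was 0.617 over members that belong to no other list. The median was -0.16 in mouse 1 (percentile 16.7 of random matched lists) and 0.16 in mouse 2 (99.97). Without a filter on low counts its adjusted p was 0.316, and without the GW3965 library of mouse 2 the list turned downward and did not pass (0.423). Fasn, the fatty acid synthase, had a log2 fold change of 0.12 ± 0.21, and Acsl3, an acyl-CoA synthetase, had 0.83 ± 0.22 and overlaps Utp14b on the same strand. Neither passed over all genes, and Acsl3 was among those that passed when adjusted over the list alone (0.0271). In the list of PPAR targets and fatty acid oxidation, 1 of 16 members rose (Ppara, also 1 when adjusted over the list alone) and 8 were positive. That list had a mean of 0.19, a median of -0.01 and a camera adjusted p of 0.0386 (adjusted p = 0.795 with an estimated correlation), and its median was -0.08 in mouse 1 (percentile 38.3) and 0.18 in mouse 2 (99.96). The call ended without a filter on low counts (0.219), without the DMSO library of mouse 2, where the direction turned (0.663), and without the GW3965 library of mouse 1 (0.313) or of mouse 2 (0.423). Among the lipid absorption and lipoprotein genes 0 of 20 passed in edgeR, at an unadjusted p under 0.05 or in DESeq2, and the sterol importer gene Npc1l1 had -0.05 ± 0.23 (list adjusted p = 0.391).

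The list of EGF receptor ligands was higher with GW3965 in the camera test (6 tested, 5 positive, median 0.40, adjusted p = 0.00430), and its adjusted p was 0.705 with an estimated correlation. Its median was 0.44 in mouse 1 and 0.27 in mouse 2. No member passed the threshold in edgeR or DESeq2, or at an unadjusted p under 0.05. Areg had 618 ± 83.0 and 805 ± 68.0 CPM (log2 fold change 0.38 ± 0.24), Ereg 70.3 ± 12.7 and 98.0 ± 19.2 CPM (0.48 ± 0.22) and Btc 185 ± 18.3 and 250.4 ± 20.6 CPM (0.43 ± 0.22), each positive in both mice. The list's call was lost without a filter on low counts (0.156), and without the DMSO library of mouse 1 (0.405), the DMSO library of mouse 2 (0.176) or the GW3965 library of mouse 2 (0.550). The bile acid and FXR list was also higher (8 of 8 tested members positive, 3 of them in both mice, none past the threshold, median 0.16, adjusted p = 0.0365; adjusted p = 0.705 with an estimated correlation). Its median was 0.50 in mouse 1 (percentile 99.8 of random matched lists) and -0.05 in mouse 2 (25.2). It did not pass with the mouse as a block (0.0737), without a filter on low counts (0.281), or without the DMSO library of mouse 1 (0.430), the DMSO library of mouse 2 (0.0991) or the GW3965 library of mouse 1 (0.736).

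Several lists of cell types and cell states passed the camera test, with medians farther from 0 in mouse 1, whose GW3965 library had the high mitochondrial share, than in mouse 2. The mitochondrial list itself was higher (13 genes, median 0.43, adjusted p = 3.98e-05; adjusted p = 0.748 with an estimated correlation), with a median of 0.92 in mouse 1 and -0.09 in mouse 2. Immune cell markers were higher (15 tested, none past the threshold, median 0.50, adjusted p = 0.000327; adjusted p = 0.748 with an estimated correlation), with 1.02 in mouse 1 and -0.22 in mouse 2. The pan-leukocyte gene Ptprc had 10.7 and 21.9 CPM with DMSO and GW3965 in mouse 1, and 12.7 and 11.5 in mouse 2. Proliferation genes were lower (20 of 24 negative, median -0.26, adjusted p = 1.38e-06), as were Wnt target genes (13 of 16 negative, adjusted p = 0.000327), and with an estimated correlation both had an adjusted p = 0.705. The proliferation list had medians of -0.46 and -0.04 in mouse 1 and mouse 2, and Mki67 had -0.06 ± 0.21. The Wnt list had -0.39 and 0.07. In these 4 lists no gene passed over all genes or adjusted over the list alone. Without the GW3965 library of mouse 1 the adjusted p was 0.313 for the mitochondrial, 0.645 for the immune, which then turned downward, 0.269 for the Wnt and 0.000183 for the proliferation list. Without the DMSO library of mouse 1 it was 0.405, 0.0527, 0.250 and 0.405 in the same order.

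Stem cell genes (13 of 19 negative, median -0.09) and enteroendocrine genes (15 of 17 positive, median 0.08) each had a camera adjusted p of 0.0386 (adjusted p = 0.795 with an estimated correlation), and with the mouse as a block the adjusted p was 0.0835 and 0.104, and without a filter on low counts 0.0580 and 0.185. The stem cell list had a median of -0.23 in mouse 1 and 0.05 in mouse 2, with 5 members negative in both mice. The enteroendocrine list had 0.19 and -0.03, with 4 members positive in both mice. Over its members that belong to no other list, the stem cell list had 0.395. The stem cell call ended without the DMSO library of mouse 1 (0.981), the GW3965 library of mouse 1 (0.313) or the GW3965 library of mouse 2 (0.178). The enteroendocrine call ended without the DMSO library of mouse 1, where the direction turned (0.589), or the GW3965 library of mouse 2 (0.569). The stem cell marker genes Lgr5 and Olfm4 had log2 fold changes of 0.01 ± 0.37 and -0.14 ± 0.21, and the enteroendocrine gene Chga had 0.04 ± 0.24. Lyz1 of Paneth cells had 0.01 ± 0.29, Muc2 of goblet cells 0.33 ± 0.20 and the enterocyte alkaline phosphatase gene Alpi -0.01 ± 0.23. None of these genes passed the test.

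The other lists were not past the threshold. Goblet genes had a camera adjusted p of 0.0823, xenobiotic (PXR and CAR) genes 0.0698, mesenchyme and endothelium genes 0.160, Paneth, colon and immediate early genes 0.314, 0.315 and 0.315, and NF-kB genes 0.525. Distal small intestine genes had 0.558, regenerative genes 0.597, retinoid, tuft and interferon-stimulated genes 0.784 each, and enterocyte, MHC class II and proximal small intestine genes 0.914 each. Unfolded protein response genes had 0.931. Counting the lipid absorption list, these 17 lists held 212 tested genes, of which 0 passed in edgeR, DESeq2 or limma-voom, none passed adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05. Since edgeR's unadjusted p ran high over all genes, these counts do not show that the genes were unchanged. For the enterocyte, MHC class II, tuft and proximal small intestine lists the test and median were below 0 and the mean above 0, and for the unfolded protein list the median was above 0 with the test and mean below. Some of these lists passed in fits without 1 library. Such fits hold unequal numbers of libraries per mouse, so a difference between the mice can appear in them as a change with GW3965. Without the GW3965 library of mouse 1, the goblet, xenobiotic, immediate early, enterocyte, proximal and unfolded protein lists passed, each higher with GW3965. The enterocyte and immediate early lists passed as higher without the DMSO library of mouse 2. Without the DMSO library of mouse 1 the enterocyte list passed as lower. The Paneth list passed as higher without the DMSO library of mouse 1 or the GW3965 library of mouse 2. With treatment held constant, camera at the preset correlation placed the enterocyte, immediate early, proximal and unfolded protein lists higher in mouse 2. It placed the Paneth list lower there. Within the mice, the enterocyte list had medians of -0.08 in mouse 1 and 0.02 in mouse 2.

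**Figure D3:**
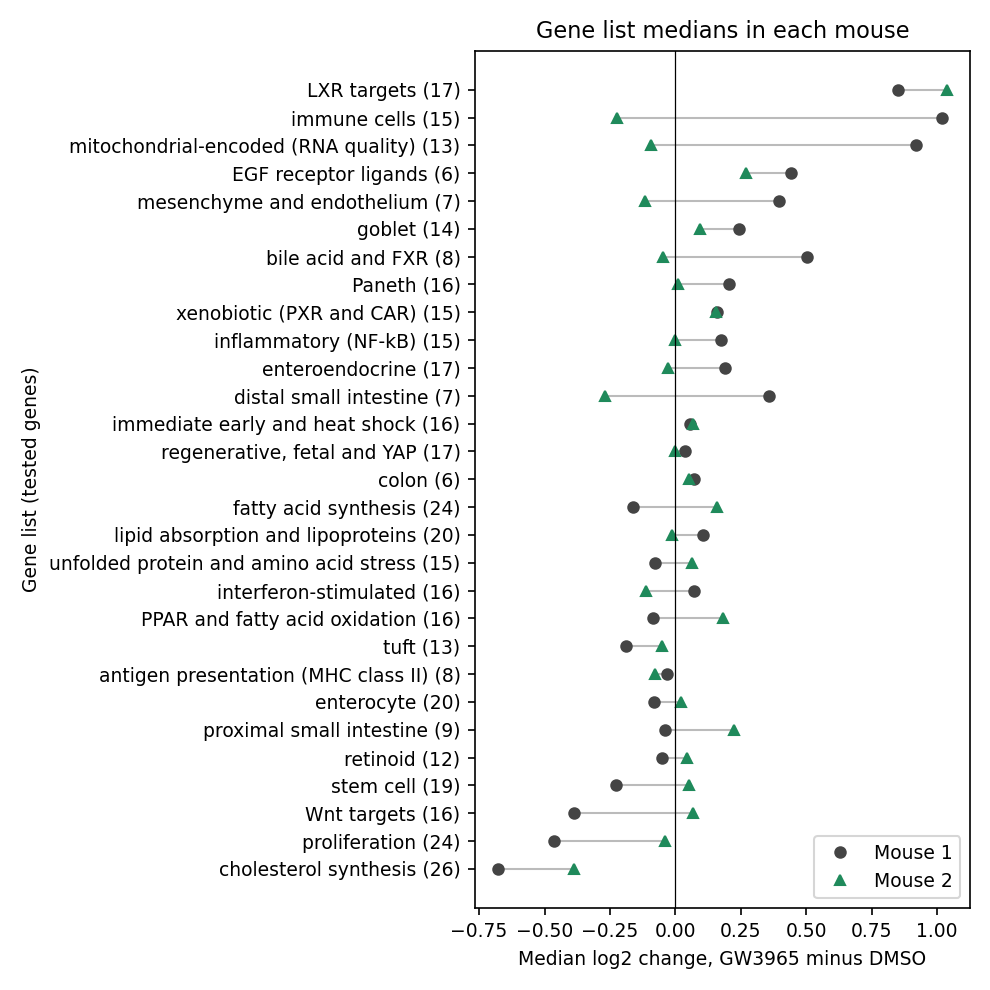
Median log2 difference between GW3965 and DMSO over the tested genes of each of 29 lists (number in brackets), in mouse 1 (circles) and mouse 2 (triangles). LXR targets lie at 0.85 and 1.04 and cholesterol synthesis genes at -0.68 and -0.39, while immune cell markers lie at 1.02 in mouse 1 and -0.22 in mouse 2.

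Across all genes the differences between GW3965 and DMSO ran in opposite directions in the 2 mice more often than in the same one. Over 11494 genes at a mean log2 CPM of at least 1, the Pearson correlation of the mouse 1 and mouse 2 differences was -0.249 and the Spearman correlation -0.456, and 31.4% of genes had the same sign. Over all 13602 tested genes these were -0.135, -0.361 and 33.5%. Across the 17 LXR targets the Pearson correlation was 0.945, the Spearman correlation 0.858, and 88.2% had the same sign. Genes are not independent replicates, and no p is given. The standard deviation of the differences was 0.43 in mouse 1 and 0.26 in mouse 2.

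The 2 mice differed from each other in 93 genes once treatment was held constant (edgeR, adjusted p under 0.05), 46 higher and 47 lower in mouse 2. Each mouse is 1 animal with 2 cultures, so the spread between animals was not measured. This fit, like the blocked one, had 1 residual degree of freedom and an infinite prior. A gene's own spread between cultures therefore did not set its p. Gm7849, higher in mouse 2 at an adjusted p of 4.46e-24, had 64.5 (DMSO) and 0.91 (GW3965) CPM in mouse 1. The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were higher in mouse 2, with a log2 fold change of 3.22 ± 0.26 for both Hba-a2 and Hbb-bs (adjusted p = 7.75e-32 and 8.66e-32). Hba-a2 shared 92.6% of its 31-mers with Hba-a1 and Hbb-bs 54.4% with Hbb-bt, so the division of reads within each pair is uncertain. Hba-a2 had 3.90 and 8.77 CPM in the DMSO and GW3965 cultures of mouse 1 and 59.0 and 52.4 CPM in those of mouse 2. Also higher in mouse 2 were Lct, the lactase (1.75 ± 0.24, adjusted p = 2.74e-10), Treh, the trehalase (1.29 ± 0.25, 0.000138), and Ace (1.17 ± 0.24, 0.000240); Treh overlaps Phldb1 on the other strand. Reg3b (-1.39 ± 0.31, 0.00185) and Reg3g (-1.26 ± 0.30, 0.00765), the matrix protease gene Mmp7 (-1.18 ± 0.25, 0.000507) and the metallothioneins Mt1 (-1.34 ± 0.29, 0.00113) and Mt2 (-1.72 ± 0.27, 1.55e-07) were lower. These genes were chosen after their values were seen. The enterocyte and cholesterol synthesis lists were higher in mouse 2 (camera adjusted p = 3.46e-09 and 5.17e-09) and the Paneth list lower (0.000569), each with an adjusted p = 0.799 with an estimated correlation. Fatty acid synthesis (0.00358), immediate early (0.00411), proximal small intestine (0.00534), unfolded protein (0.00612), enteroendocrine (0.0116) and MHC class II genes (0.0120) were also higher, and PPAR (0.00163) and immune cell genes (0.0116) lower. These lists too had an adjusted p = 0.799 with an estimated correlation. Without treatment in the model 10 genes passed, 5 in each direction, and DESeq2 called 28.

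At the level of single transcripts, 0 of 32357 tested transcripts passed in edgeR's quasi-likelihood test. The lowest adjusted p of any transcript in that test was 0.784. At an unadjusted p under 0.05 there were 846, a share under the 0.05 that a calibrated test gives when no transcript changes. The count of 0 thus does not show that the transcripts were unchanged. DESeq2 called 195, 98 higher and 97 lower. The biological coefficient of variation was 0.545 for transcripts and 0.188 for genes. Among the transcripts of Srebf1, ENSMUST00000144942 had 4.25 ± 0.96 TPM, kallisto's length-scaled abundance, with DMSO and 46.3 ± 16.6 with GW3965 (n = 2 each, log2 fold change 3.51 ± 0.32, adjusted p = 0.784). ENSMUST00000020846 had 13.5 ± 0.08 and 49.1 ± 14.8 TPM (1.92 ± 0.24, adjusted p = 0.784). The share of the first in the gene's TPM was 8.55% with DMSO and 16.8% with GW3965, and that of the other was 26.9% and 17.8%; the difference in shares was not tested.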

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

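The test of the mitochondrial share by the immune cell list was chosen after its result was seen, and the patterns were found in the same data. The results below stand out because the 2 mice moved in opposite directions. None of these differences between the mice was tested, since 1 library per mouse and treatment leaves no spread for an interaction. The mitochondrial share of counts was 6.41 percentage points higher with GW3965 than with DMSO in mouse 1, and the difference was -0.689 points in mouse 2. The median log2 change of the mitochondrial list was 0.919 in mouse 1 and -0.0938 in mouse 2. Among 10000 random lists matched on expression these lay at percentile 100 and 7.18. Immune cell markers had medians of 1.02 in mouse 1 (percentile 100) and -0.22 in mouse 2 (3.965). Markers of the distal small intestine had 0.36 in mouse 1 (96.5) and -0.27 in mouse 2 (0.36), farther out in mouse 2. Those of the proximal small intestine, given beside them for comparison, had -0.04 in mouse 1 (64.1) and 0.22 in mouse 2 (100). Against the random lists, the proximal list thus did not move in opposite directions.

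The GW3965 library of mouse 1 stood apart from the other 3, and its difference from the DMSO library of the same mouse had a standard deviation of 0.427 over genes, against 0.256 in mouse 2. Among abundant nuclear genes chosen after their values were seen, it was above the mean of the others for Rpl34 (log2 0.83) and Fabp2 (0.81). It was below that mean for Cdh1 (-0.81) and Vil1 (-0.65). A larger mitochondrial share that takes counts alike from every nuclear gene would move those genes by 1 factor. Such a factor cannot by itself shift the immune cell markers (median 1.02 in mouse 1) against other nuclear genes. The list was chosen after its result was seen, so its place above all 10000 random lists is not counted as support. Leaving out the mitochondrial genes, the test chosen before, gave a standard deviation of 0.4412 and decided nothing, because it moved every other gene by nearly the same factor. That shift had a standard deviation of 0.000116 over genes, so 0.4412 and 0.427 rest on different sets of genes past the expression cut. A trend with GC content and transcript length is argued against as the whole cause, because 0.4046 remained after its removal. A response to GW3965 that mouse 1 alone gave and an effect of handling that 1 culture cannot be told apart with 1 library per mouse and treatment, and both may contribute.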

How the results depend on the processing

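The settings that keep protein-coding genes alone, leave out mitochondrial genes or combine the block with another choice were added after seeing the data. Against 8 genes changed by GW3965 (8 higher, 0 lower), library size alone gave 13 (1 lower), DESeq2 20 (17 higher, 3 lower), the likelihood ratio test 29 (20 and 9), limma-voom 20 (14 and 6), no filter 14 (2 lower), the stricter filter 12 (1 lower), DESeq2 with the replicate block 12 (1 lower), protein-coding genes alone 10 (1 lower), the replicate block 48 (31 and 17) and the block with protein-coding genes alone 29 (18 and 11). Leaving out 1 library gave 38 to 84 genes, 28 to 57 higher and 10 to 27 lower; the lone library left in a group is then assumed to vary like the other group. limma on the authors' log2 CPM called 0 genes, 0 higher and 0 lower (unadjusted p under 0.05 for 146 higher and 213 lower). The cause of these shifts was not tested. The 7 named genes stayed called in each setting except the authors' log2 CPM (0 of 7, with positive log2 fold changes from 1.62 to 4.62) and without DMSO replicate 2 (6 of 7). Gm16378 lost its call with the rounded counts (adjusted p = 0.0512) and with DESeq2 and the block, and was not tested among protein-coding genes. Among the scalings, the median of all genes moved most with library size alone, to a log2 value of -0.0205.

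Of 29 lists, 12 passed in camera, 0 with an estimated correlation, with fry or with the block and an estimated correlation, 6 without a filter and 6 to 12 when 1 library was left out. The LXR list had an adjusted p of 0.200 with an estimated correlation, 0.103 with fry and 0.659 with the block and an estimated correlation. Lists changed direction when 1 library was left out, with adjusted p from 2.60e-09 to 0.423 for fatty acid synthesis, 9.88e-09 to 0.663 for PPAR, 0.00405 to 0.589 for enteroendocrine, 0.00144 to 0.140 for enterocyte, 0.00520 to 0.495 for unfolded protein, 0.000137 to 0.645 for immune and 0.0404 to 0.637 for proximal small intestine genes. Among the genes and lists named in the report, the block changed no call beyond those given there. DESeq2 called 195 transcripts (98 higher, 97 lower) against 0. For the 93 genes that differed between the mice (46 higher, 47 lower in mouse 2), the fit without treatment gave 10 (5 and 5), DESeq2 28 (12 and 16) and protein-coding genes alone 60 (24 lower); no library could be left out of that fit, which would keep no residual degree of freedom. At this depth and group size the test recovered 61% of simulated 2-fold changes, so these and smaller ones can be missed. The simulation held no mouse effect and no outlying library, so recovery in the data can be lower.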

Other observations

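The tests of the mouse 1 library and of proliferation as sources of the lower cholesterol synthesis genes were chosen after the result was seen. Of the 48 genes called with the mouse as a block, 8 were also called without it. Some of the rest are described here, chosen after their values were seen. DESeq2 with the block called 12 genes in all. Rnf186, a ubiquitin ligase gene of the gut epithelium, had 42.5 ± 8.82 CPM with DMSO and 93.3 ± 3.71 with GW3965 (SD, n = 2 each; log2 fold change 1.13 ± 0.21, edgeR adjusted p = 0.198, blocked 0.00127). Cyp2w1, a cytochrome P450 gene, had 1.31 ± 0.40 and 5.78 ± 1.65 CPM (2.14 ± 0.38, 0.198, blocked 5.88e-05). Slc5a6, a vitamin transporter gene, had 5.40 ± 0.14 and 1.12 ± 0.48 CPM (-2.27 ± 0.39, 0.165, blocked 2.03e-05), and it overlaps Atraid on the other strand. Utp14b had 45.6 ± 1.58 and 88.7 ± 13.2 CPM (0.96 ± 0.19, 0.338, blocked 0.0276); it lies inside Acsl3 on chromosome 1 on the same strand, so the reads of the 2 genes are not cleanly separated. The EGF receptor ligand genes Ereg (91074622 to 91093646), Areg (91139599 to 91148432) and Btc (91357261 to 91402994), lie near each other on chromosome 5.

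The cholesterol synthesis list was lower with GW3965 in both mice. The GW3965 library of mouse 1 as its only source is argued against by mouse 2, where the median was -0.3861 (percentile 0 of random matched lists). That percentile leaves out the correlation between the list's members. With treatment held constant, the list differed between the mice by a median of 0.387, higher in mouse 2. Whether the fall in mouse 2 exceeds the spread between cultures was not measured. A trend with GC content and length is argued against by the median of -0.416 in mouse 2 after its removal (percentile 0). Fewer proliferating cells are argued against as the whole cause, since the proliferation list had a median of -0.0389 in mouse 2 (percentile 12.5). The treatment itself stays open as an explanation, and the list's call was lost with an estimated correlation (adjusted p = 0.705).

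Genes at 0 counts in both libraries of 1 treatment and at 10 or more in each library of the other numbered 13 (7 at 0 with DMSO, 6 with GW3965), of which the blocked fit called all 13 and the unblocked fit 1. The same pattern appeared in 8 genes between the mice and in 6 between crossed pairs of libraries. Reads shared with near-identical copies are a candidate source, since 11 of the 13 (84.62%) shared over 50% of their 31-mers with another gene, against 45 of 130 genes matched on expression (34.6%). Summed with the genes that share their sequence, 11 of them changed by a median size of 0.0629 on the log2 scale, although abundant relatives dominate those sums. Mapre3 and Tmem143 shared 0% with the matched transcripts and stay open, because the 2079 unmatched transcripts were not searched.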
